A study of Mus musculus with 4 samples.

How the data were processed

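Retinas of 2 WT and 2 NLGF mice, 1 female and 1 male of each, were dissociated and loaded on a droplet-based single-cell RNA-seq platform (10x Genomics), 1 library per retina, per the labels' protocols. Age was 30 days. Each library is 1 animal, so the spread between libraries holds both animal and preparation differences. The labels give genotype and sex, and do not give litters or sequencing batches.

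The authors deposited raw UMI counts per gene and barcode, as 1 matrix per library with 32285 genes. Cell Ranger 6.1.1 wrote these matrices, per the file headers, whereas the submitters' processing notes name Cell Ranger 3.1.0 with STAR and the mm10 build. Both are given here because the sources differ. The lowest barcode total was 500 UMIs in each library. Whether intronic reads were counted is not given in the sources used here. Gene positions were taken from GENCODE M21 on GRCm38, the assembly also called mm10, where 32158 of the 32285 gene IDs matched. Where several gene IDs shared a symbol, the symbol was kept for the ID with most UMIs.

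The files held 35191 barcodes and 85860041 UMIs, with median UMIs per barcode of 945.5 (WT female), 1168.5 (WT male), 1005 (NLGF female) and 1054 (NLGF male). Barcodes with at least 300 genes and at most 20% mitochondrial UMIs were kept, which left 33329. Scrublet scores were computed per library at an expected doublet rate of 6%. The automatic threshold marked 13 cells, too few for a working call, so cells scoring in the top 6% of their library were removed (1796 cells). The remaining 31533 cells were scaled to 10000 UMIs and log transformed. Then 2000 variable genes, 30 principal components, 20 neighbours and Leiden clustering at resolution 1 gave 29 clusters.

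Clusters were named from marker genes fixed before the data were examined, which also applies to the groups, the tests, the gene lists and most of the alternatives. A cluster took the class of highest mean marker z-score among those with at least 3 detected markers, or another such class with more markers among the cluster's top 10 genes by fold. With no marker among the top 10 genes and a mean z-score under 0.8 it stayed unnamed. That z threshold was set after the data were seen. Classes carry names such as Müller glia on this marker basis alone, and read as Müller-like, rod-like and so on. The 10 named classes left 2 clusters unnamed, with 146, 257, 138 and 147 cells (1.79%, 3.16%, 1.91% and 1.83%) in the WT female, WT male, NLGF female and NLGF male. The Müller class joined 3 clusters with median UMIs of 797, 10056 and 2315 per cell.

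Counts were summed per library and class, for classes with at least 10 cells in every library. NLGF was compared with WT with edgeR's quasi-likelihood test (TMM factors, filterByExpr, genotype as the only term, Benjamini-Hochberg adjustment, threshold 0.05). Standard errors are the absolute log2 fold change divided by the square root of the F statistic, and CPM values use the TMM factors unless they are given over all cells, from raw counts or for microglia. The difference between Müller glia and rods was an interaction term with library as a block. Gene lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, two-sided and adjusted over the lists of a class, beside camera with an estimated correlation and fry. Cell numbers were tested with edgeR without TMM. The p-values rest on 2 libraries per genotype.

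Genes were named by a fixed rule. In Müller glia it took the 12 largest changes in each direction among genes past the threshold that changed alike in both sexes, whose class mean CPM was at least 0.5 times that over all cells, and that were not sex-linked, mitochondrial or unnamed gene models. Other classes and the interaction took 5 per direction, and in these classes directions with fewer were filled up to 3 with the smallest p. App, Hspa5, Ddit3, Atf4, Xbp1, Gfap, up to 12 members of the PERK/ATF4 and ER chaperone lists with an unadjusted p under 0.05 and up to 4 members of each list called by camera were also named. Outside this rule, Phgdh, Eif2ak3, Sec61b, Slc14a1, Socs3, Vim, Ier3, Ifitm3, Gm42418, the microglial genes, and Mt2 in Müller glia were named after their values were seen. For genes with 0 UMIs in a group, fold bounds use a floor of 3 counts over the group and cover counting error only.

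The test was checked on simulated counts, with 200 genes changed by 1.5, 2 or 4 times. Counts were drawn per library and class from a negative binomial with the real means, library totals and dispersion trend. Genes did not differ in spread beyond that trend, and single cells with high counts were not simulated. The rates below therefore do not cover genes carried by 1 or a few cells, and may be too favourable. In Müller glia 21.2%, 60.3% and 93.7% of the changed genes were recovered at these folds, with 3 of 114 calls on unchanged genes. In rods the values were 53.1%, 86.4% and 100%, in cones 16.9%, 73.8% and 95.3%, in rod bipolar cells 27%, 69.7% and 96.7%, in cone bipolar cells 55.4%, 76.1% and 98.5%, and in amacrine cells 35.8%, 61.9% and 98.5%. In endothelial cells they were 1.6%, 28.1% and 84.8%, and for the difference between Müller glia and rods 10.4%, 49.3% and 87.9%. Camera was checked in simulated Müller counts on a list of 20 genes raised 2-fold. Its unadjusted p was 1.13e-37 at the preset correlation and 0.0135 with an estimated one. Of 100 random lists of unchanged genes, 0 had a p under 0.05 at either setting. Genes were drawn independently, so this check could not show false calls from correlated genes. In rods the estimated correlation was 0.98 for mitochondrially encoded genes, 0.74 for ribosomal proteins and 0.61 for the respiratory chain. A list call lost with an estimated correlation can therefore reflect correlated genes or low power, and does not show that the list stayed level.

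Alternatives were RLE size factors, no filter on low counts, sex as a block, counts thinned to the smallest library, doublets kept, at least 600 genes and at most 10% mitochondrial UMIs, resolution 2, components centred per library, DESeq2, and leaving out each library. Subsets of Müller glia and rods were added after the data were seen. Python 3.11.15 with scanpy 1.11.5, leidenalg 0.10.2 and numpy 2.4.6, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 were used.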

Results

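Single-cell transcriptomes were collected from dissociated mouse retina at 30 days of age. The 4 libraries came from 2 wild-type (WT) mice and 2 NLGF mice, with 1 female and 1 male of each genotype and 1 retina per mouse. NLGF mice carry a knock-in App allele with humanised and mutated amyloid beta sequence. App encodes the amyloid precursor protein. The study's title places an endoplasmic reticulum (ER) stress response in Müller glia, the radial glia that span the retina. The comparison of NLGF with WT in each cell class asks which transcripts differ at this age and in which cells.

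The files held 9058 barcodes for the WT female, 9068 for the WT male, 8060 for the NLGF female and 9005 for the NLGF male. Total counts of unique molecular identifiers (UMIs) were 20842178, 23473093, 19128388 and 22416382 in the same order. After filtering, 31533 cells remained, in 29 clusters. Rods made up 81.9% ± 1.51 of WT cells and 82.2% ± 0.0855 of NLGF cells (SD, n = 2 each). Müller glia numbered 247, 381, 411 and 382 cells in the WT female, WT male, NLGF female and NLGF male. Their median UMI counts per cell were 4201, 1733, 2182 and 3463.5. Summed per library, the Müller class held between 1285602 and 2070323 UMIs.

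Xist, the RNA that silences an X chromosome, had 2128 and 2056 CPM (UMIs of a gene per 1e+06 UMIs) over all cells in the WT and NLGF females, with 0 UMIs and 2 UMIs in the WT and NLGF males. The Y-linked gene Ddx3y had 0 UMIs in both females, 1651 in the WT male and 1510 in the NLGF male, and Eif2s3y had 0 UMIs in both females, 3351 UMIs in the WT male and 2907 in the NLGF male. The sexes given by the labels therefore matched these counts. App (ENSMUSG00000022892, GRCm38 chromosome 16, 84949685 to 85173766, minus strand) had 241, 237, 203 and 234 CPM over all cells of the WT female, WT male, NLGF female and NLGF male. These counts do not tell the edited from the unedited allele, so they do not check the knock-in. Within Müller glia the App log2 fold change of NLGF over WT was −0.07 ± 0.11 (SE, n = 2 per genotype, edgeR adjusted p = 0.888). In the other classes it was −0.43 ± 0.16 in rods, 0.34 ± 0.27 in cones, 1.01 ± 0.63 in rod bipolar, −0.04 ± 0.07 in cone bipolar, −0.23 ± 0.10 in amacrine and −0.15 ± 0.17 in endothelial cells, with edgeR adjusted p from 0.519 to 0.999.

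In Müller glia, genes of the PERK/ATF4 integrated stress response were higher in NLGF than in WT retina. Atf4, the transcription factor translated when eIF2-alpha is phosphorylated, rose from 80.5 ± 4.84 to 214 ± 18.0 CPM (SD, n = 2 per genotype), a log2 fold change of 1.42 ± 0.11 (SE, edgeR adjusted p = 2.67e-07). Ddit3, which encodes the stress-induced factor CHOP, rose from 63.3 ± 12.3 to 223 ± 2.10 CPM, and Atf5, a related transcription factor, from 55.7 ± 10.4 to 240.0 ± 4.76 CPM. Their log2 fold changes were 1.78 ± 0.12 (edgeR adjusted p = 4.32e-08) and 2.08 ± 0.12 (edgeR adjusted p = 8.41e-09). Chac1, an enzyme that breaks down glutathione, had 0 UMIs in WT Müller glia and 79 in NLGF, at least 21.3-fold higher against a floor of 3 counts over the group.

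Of the 22 genes in the PERK/ATF4 list, 20 were measured in Müller glia, 11 rose, 0 fell and 14 rose when adjusted over the list alone. Besides Atf4, Ddit3, Atf5 and Chac1, the risen genes were Trib3, a pseudokinase induced by CHOP (log2 fold change 4.03 ± 0.93), and Mthfd2, a mitochondrial folate enzyme (3.36 ± 0.28). They also included the transcription factors Atf3 (3.02 ± 0.67) and Cebpg (1.45 ± 0.12), the stress protein Nupr1 (1.58 ± 0.11), Sesn2, a leucine-sensing repressor of mTORC1 (1.93 ± 0.33), and the amino acid transporter Slc7a5 (1.43 ± 0.22). The Atf3 call was lost without the WT male, NLGF female or NLGF male (edgeR adjusted p = 0.0556, 0.45 and 0.375) and with DESeq2 (0.586). The Trib3 call was lost without the WT female (0.0594), with doublets kept (0.0616) and with DESeq2 (0.784), and Trib3 was not tested without either NLGF library and had 6.46 without the WT male. The Sesn2 call was lost without the NLGF male (0.0654) and with DESeq2 (0.0693), and the Slc7a5 call with doublets kept (0.194). Without a filter on low counts the Trib3, Atf3, Sesn2 and Slc7a5 calls were lost (edgeR adjusted p = 0.19, 0.134, 0.0694 and 0.0582). With counts thinned to the smallest library, the Trib3 and Atf3 calls were not kept. Phgdh, of serine synthesis, had 0.81 ± 0.20 and an edgeR adjusted p of 0.0561. The kinase gene Eif2ak3, which encodes PERK itself, had −0.42 ± 0.29. PERK activity was not measured, so these transcripts do not show that PERK caused the rise. The median log2 fold change of the list was 1.42, also with Chac1 set at its bound. The list moved against the other genes with camera at a preset correlation (adjusted p = 1.25e-15). The camera adjusted p was 0.258 with an estimated correlation (unadjusted p = 0.0117), and fry, which tests the list on its own, gave 0.0152. With an estimated correlation a simulated list of 20 genes raised 2-fold had an unadjusted camera p of 0.0135, so that setting had little power here. For orientation on GRCm38, Atf4 lies on chromosome 15 (80255184 to 80257541), Ddit3 on chromosome 10 (127290774 to 127296288), Atf5 on chromosome 7 (44812256 to 44816658) and Chac1 on chromosome 2 (119351229 to 119354381). All 4 are protein-coding genes.

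The ER chaperones and ATF6/XBP1 targets showed no such shift in the same cells. Of 28 listed genes 27 were measured, 1 rose and 1 fell, and adjusted over the list alone 2 rose and 2 fell. The risen gene was Herpud1, a component of ER-associated degradation that ATF4 also induces, with 109 ± 5.17 CPM in WT and 238 ± 4.45 in NLGF (log2 fold change 1.13 ± 0.10, edgeR adjusted p = 7.8e-07). The fallen gene was Sec61b, a subunit of the ER translocon (−0.45 ± 0.10, edgeR adjusted p = 0.0418), a call lost with DESeq2 and without the WT male, NLGF female or NLGF male. Hspa5, the main ER chaperone BiP (chromosome 2, 34771970 to 34777547), had 293 ± 8.98 CPM in WT and 237 ± 3.73 in NLGF, with a log2 fold change of −0.31 ± 0.10 and an edgeR adjusted p of 0.18. Xbp1, the factor spliced by IRE1, had −0.05 ± 0.16 and an edgeR adjusted p of 0.959. The list's median was 0.05 and its mean 0.03, while camera gave the direction down (adjusted p = 0.848, and 0.96 with an estimated correlation).

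**Figure D1:**
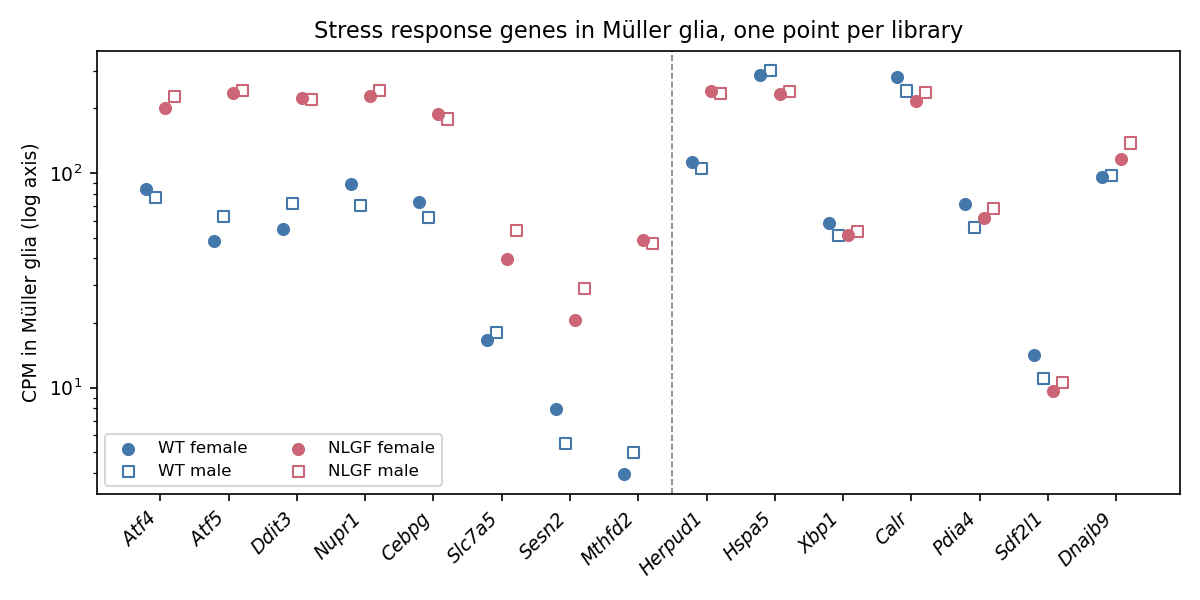
CPM in Müller glia on a log axis for genes of the PERK/ATF4 list (left of the dashed line) and the ER chaperone list (right), 1 point per library, circles for females and squares for males. Each NLGF point lies above both WT points for the 8 genes on the left and for Herpud1, while Hspa5 had 293 CPM in WT and 237 in NLGF.

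Over all genes, 119 of the 11140 tested in Müller glia differed between genotypes with edgeR at an adjusted p threshold of 0.05, 65 higher and 54 lower in NLGF, and 1169 had an unadjusted p under 0.05. All 119 differed in the same direction between the females and between the males, as did all called genes in the other classes. These pairs are the same libraries that gave the calls, so the shared direction is largely set by the test and is no separate support. Other risen genes with the largest changes were Slc7a1, a cationic amino acid transporter (log2 fold change 3.07 ± 0.38), and Cdkn1a, the cell cycle inhibitor p21 (2.88 ± 0.32). They also included Cebpa, a transcription factor (2.51 ± 0.54), Eif4ebp1, a repressor of cap-dependent translation (2.07 ± 0.22), Aldh18a1, of proline synthesis (2.01 ± 0.34), and Cars, the cysteinyl-tRNA synthetase (1.99 ± 0.27). Hist1h2ap had 2.09 ± 0.21, a value that is uncertain because near-identical histone genes share reads. The Cebpa call was lost without the WT male, NLGF female or NLGF male (edgeR adjusted p = 0.0722, 0.0782 and 0.62) and with DESeq2 (0.475), and the Aldh18a1 call with DESeq2.

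The count of changed genes in Müller glia moved with the libraries and the tool. It was 260 without the WT female, 256 without the WT male, 88 without the NLGF female, 70 without the NLGF male and 45 with DESeq2. With edgeR it was 26 without a filter on low counts, 76 with counts thinned to the smallest library, 200 with doublets kept and 217 with sex as a block. In the Müller cluster with the fewest UMIs per cell, tested alone, edgeR called 0 of 3764 genes, with 172 at an unadjusted p under 0.05, and DESeq2 was not run there.

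Some astrocyte-associated genes were lower in NLGF Müller glia, mostly through the WT female, and were not tested as a group. Slc14a1, also among the astrocyte markers fixed beforehand, went the other way and was among the genes higher in NLGF. Its call was lost with DESeq2, without the NLGF male and without a filter on low counts, and it was not used to pick the astrocyte-marker cells below. Gfap, the glial intermediate filament, had 108 ± 138 CPM in WT and 4.58 ± 0.328 in NLGF (log2 fold change −4.38 ± 0.93, edgeR adjusted p = 0.022). Pdgfra, a growth factor receptor of retinal astrocytes, had −4.58 ± 0.90, the calcium-binding protein S100b −2.38 ± 0.56 and the growth factor binding protein Igfbp5 −2.31 ± 0.52. Between the males the log2 differences were −1.03 for Gfap, −0.40 for S100b and −0.37 for Igfbp5. Without the WT female the log2 fold changes were −1.12 for Gfap, −0.59 for S100b and −0.50 for Igfbp5 (edgeR adjusted p = 0.368, 0.545 and 0.433), and −1.90 for Pdgfra (0.0472). DESeq2 called 0 of these 4 genes, and with doublets kept the Gfap call was lost (edgeR adjusted p = 0.0861). Cells with at least 10 Gfap UMIs numbered 3 in the WT female, 1 in the WT male, 0 in the NLGF female and 0 in the NLGF male. Müller-class cells with UMIs of at least 2 of the astrocyte markers Gfap, Pax2, Pdgfra, Igfbp5 and S100b numbered 9, 8, 6 and 9. In the WT female these cells held 96.1% of Gfap UMIs and in the WT male 95%.

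Other genes with large falls included Glycam1, a mucin-like glycoprotein (−7.16 ± 1.31), Cnmd, a chondromodulin (−3.93 ± 0.74), A2m, a protease inhibitor (−3.43 ± 0.62), and Cst3, the protease inhibitor cystatin C (−2.34 ± 0.39). In the WT female the values of these 4 genes rest on a few cells. The astrocyte-marker cells there held 97.4% of Glycam1, 100% of Cnmd, 95.7% of A2m and 88.5% of Cst3 UMIs, and 1 cell held 111 of 116 Glycam1 UMIs. In the WT male the marker cells held 69.2%, 86.7%, 35% and 32.6% in the same order. Cst3 UMIs lay in 256 of 381 cells of the WT male. Adamts19, a metalloprotease, fell from 18.5 ± 1.49 to 1.45 ± 0.685 CPM (−3.63 ± 0.46, edgeR adjusted p = 1.65e-04), and Cyp26b1, which degrades retinoic acid, had −2.73 ± 0.56. Eya2, a transcriptional coactivator, and Cd36, a fatty acid receptor, each had 24 UMIs in WT and 0 in NLGF, at least 9.87-fold lower against the floor of 3 counts. Eya2 UMIs lay in 8 cells of the WT female and 9 of the WT male, whereas all Cd36 UMIs lay in astrocyte-marker cells, with 10 of 13 in 1 cell of the WT female and 9 of 11 in 1 cell of the WT male. Without the astrocyte-marker cells, a choice made after the data were seen, 115 genes differed (71 higher, 44 lower). Of the 119 genes, 98 remained past the threshold, among them Adamts19 (−3.59 ± 0.48), Cyp26b1 (−2.73 ± 0.55) and Eya2, while Igfbp5 turned to 0.18. The Adamts19 call held without each library and with DESeq2. The Cyp26b1 call was lost without the WT female, NLGF female or NLGF male (edgeR adjusted p = 0.0797, 0.09 and 0.06) and with DESeq2 (0.0878). The Eya2 and Cd36 calls were lost without each library in turn, and the Cnmd (0.0535) and Glycam1 calls without the WT female. Cst3 had −0.84 without the WT female, and −0.37 without these cells, where its call was lost (0.148). With DESeq2 the Cst3, A2m and Glycam1 calls were lost (adjusted p = 1, 0.165 and 0.238). Without the astrocyte-marker cells, 7 of the 119 genes had too few counts to be tested, among them Gfap, Pdgfra, Glycam1, Cnmd, A2m and Cd36.

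**Figure D2:**
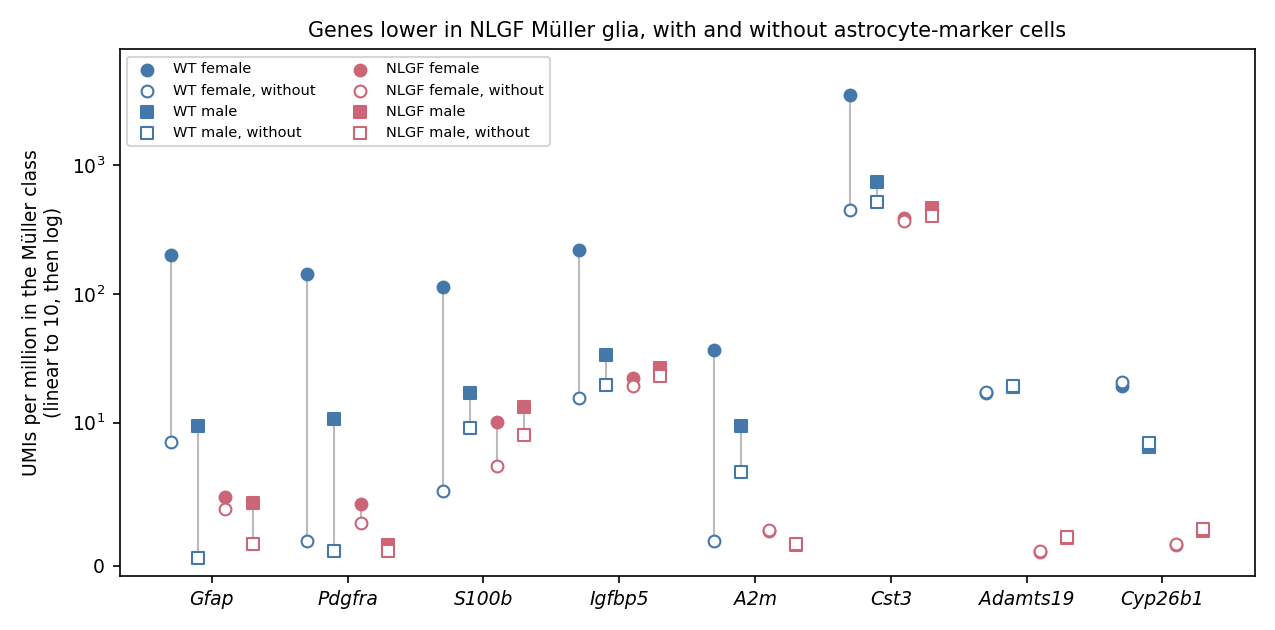
CPM from raw counts in the Müller class for 8 genes that were lower in NLGF, on an axis that is linear to 10 and then logarithmic, for each library with all cells (filled) and without the astrocyte-marker cells (open). Leaving out these cells lowers Gfap, Pdgfra, S100b, Igfbp5, A2m and Cst3 in the WT female, and leaves Adamts19 and Cyp26b1 close to their values.

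The gliosis list had 13 measured genes in Müller glia, of which 0 rose and 3 fell (also 3 when adjusted over the list alone): Gfap, A2m and Socs3, a feedback inhibitor of cytokine signalling (−1.43 ± 0.28, lost without the NLGF male and with DESeq2). Its camera adjusted p was 0.417 and its median −0.10, and Vim, an intermediate filament, had 0.03 ± 0.11. In the p53 and apoptosis list 2 of 12 genes rose, Cdkn1a and Phlda3 (1.01 ± 0.23), and also 2 when adjusted over the list alone. The Phlda3 call was lost without the WT male, NLGF female or NLGF male and with DESeq2. The list's camera result passed only at the preset correlation (median 0.35, camera adjusted p = 0.00917, adjusted p = 0.675 with an estimated correlation). The proapoptotic gene Bbc3 had 1.47 ± 0.57 with an edgeR adjusted p of 0.334. The circadian clock list had a median of 0.21 over 14 genes, with 0 past the threshold and 5 risen when adjusted over the list alone. Its camera adjusted p was 0.014, with an adjusted p of 0.675 with an estimated correlation, and Dbp, a clock output factor, had 0.42 ± 0.10.

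Metabolic and retinoid lists had medians below 0 in Müller glia. The retinoid cycle list had a median of −0.32 over 11 genes, of which 1 fell, a call lost without the NLGF male, and 5 fell when adjusted over the list alone. Rgr and Rdh5, with −1.23 ± 0.44 and −1.25 ± 0.48, did not pass over all genes. Glycolysis had a median of −0.16 over 18 genes, with 1 fallen, the phosphofructokinase Pfkl (−0.45 ± 0.10), and 3 fallen when adjusted over the list alone. The mitochondrially encoded genes had a median of −0.21 over 13, with 1 fallen, mt-Atp8 (−0.48 ± 0.10), and 4 when adjusted over the list alone. The nuclear-encoded respiratory chain had −0.09 over 90 genes, with 1 fallen, Ndufa4l2 (−1.51 ± 0.30), also 1 when adjusted over the list alone. The Pfkl call was lost without the NLGF female or NLGF male (edgeR adjusted p = 0.173 and 0.328) and with DESeq2 (0.711), and the mt-Atp8 call without the NLGF female or NLGF male (0.481 and 0.459). The Ndufa4l2 call was lost without the NLGF male (0.0941) and with DESeq2 (0.327). Cholesterol synthesis (median −0.12, 20 genes) and presynaptic genes (median −0.17, 16 genes) had 0 changed genes with edgeR, also 0 when adjusted over the list alone. Idi1, of cholesterol synthesis, had −0.47 ± 0.14 (unadjusted p = 0.0028), and Unc13b, a priming factor of synaptic vesicles, had −0.36 ± 0.16 (unadjusted p = 0.0345). Camera adjusted p was 0.0216 for the retinoid cycle, 0.00378 for mitochondrially encoded genes and 0.0475 for presynaptic genes. It was 0.014 for cholesterol synthesis, glycolysis and the respiratory chain. With an estimated correlation the adjusted p was 0.866 for each of these 6 lists.

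The remaining lists did not move in Müller glia by camera. The immediate early genes (adjusted p = 0.916) had 1 riser, Atf3, and 1 faller, Ier3 (−0.81 ± 0.16), among 14, and 2 of each when adjusted over the list alone. Their median was −0.25, while their mean was 0.04 and camera gave the direction up. The interferon and antigen presentation list (0.417) had 1 faller, Ifitm3 (−1.65 ± 0.33), also 1 when adjusted over the list alone, and the oxidative stress and metallothionein list (0.588) had 1 riser, Mt2 (0.46 ± 0.09), and 2 when adjusted over the list alone. With DESeq2 the Atf3, Ier3, Ifitm3 and Mt2 calls were lost. So were the Ier3 call without the WT female or NLGF male, the Ifitm3 call without the NLGF male and the Mt2 call without the WT male, NLGF female or NLGF male. Adjusted p was 0.926 for Müller glia homeostasis, 0.417 for cytosolic heat shock, cytosolic ribosomal proteins and cone phototransduction, and 0.799 for rod phototransduction. In the homeostasis list 2 genes rose when adjusted over the list alone. Adjusted p was 0.908 for APP processing and clearance, with a median of −0.01, a mean of 0.01 and the direction down, and 0.848 both for disease-associated microglia genes and for lysosome and autophagy. The crystallin and homeostatic microglia lists had fewer than 5 measured genes in each class and were not tested.

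In rods, 5 of 12450 genes differed (4 higher, 1 lower, edgeR), with 1095 at an unadjusted p under 0.05 and 3 by DESeq2. The 4 higher genes were the haemoglobin genes Hbb-bt (log2 fold change 4.43 ± 0.43), Hba-a2 (4.19 ± 0.40), Hba-a1 (3.93 ± 0.37) and Hbb-bs (20.9 CPM in WT and 379 in NLGF), transcripts of red blood cells whose close copies can share reads. All 4 calls were lost with doublets kept and with centred components, and those of Hbb-bt and Hbb-bs with DESeq2. Of the 7491 haemoglobin UMIs in NLGF female rods, 7176 lay in 1 cell, and of the 3591 in NLGF male rods 3374 lay in 1 cell. Klhl23, a kelch-like adaptor, fell from 71.1 ± 4.72 to 40.3 ± 1.55 CPM (−0.82 ± 0.09, edgeR adjusted p = 0.00279). Klhl3 (−0.55 ± 0.10) and the centrin Cetn3 (−0.43 ± 0.08) did not pass, with edgeR adjusted p of 0.161 and 0.18. The PERK/ATF4 list had a median of 0.13 over 17 genes in rods, with 0 changed by edgeR (camera adjusted p = 0.13).

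Several lists had medians below 0 in NLGF rods, with 0 genes past the edgeR threshold over all genes. These were the respiratory chain (median −0.24, camera adjusted p = 1.01e-13), ribosomal proteins (−0.21, 4.42e-10), mitochondrially encoded genes (−0.36, 2.93e-05), rod phototransduction (−0.16, 2.02e-05), cone phototransduction (−0.31, 5.92e-04) and glycolysis (−0.09, 0.0364). All of these calls were lost with an estimated correlation (adjusted p = 0.844, and 0.892 for glycolysis), as was that of the immediate early genes (median 0.13, 0.0482, and 0.844 when estimated). Between the males the medians were −0.33 for the respiratory chain, −0.31 for ribosomal proteins and −0.50 for mitochondrially encoded genes, against −0.13, −0.11 and −0.17 between the females. The WT male stood apart in its rods, with 7.33% mitochondrial UMIs against 5.85%, 5.34% and 5.61% in the WT female, NLGF female and NLGF male, and with 1097 cells in 1 rod cluster against 143, 440 and 542. Adjusted over the list alone, 10 mitochondrially encoded and 2 cone phototransduction genes fell, and 0 in the other 5 lists. Members included the phosphodiesterase subunit Pde6g (−0.35 ± 0.11), mt-Nd2 (−0.40 ± 0.12) and Ndufs8 (−0.35 ± 0.08). The number of changed genes in rods rested on single libraries, with 1069 without the WT female, 149 without the WT male, 20 without the NLGF female and 52 without the NLGF male. It was 104 without a filter on low counts, 133 with sex as a block, 254 with the stricter cell filter, and 1 with doublets kept and with centred components.

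Cones, rod bipolar and cone bipolar cells had 0 changed genes with edgeR. At an unadjusted p under 0.05 there were 518 of 9486, 579 of 9375 and 674 of 11549 genes, and DESeq2 called 0, 0 and 12. The 12 are adjusted over fewer genes, since DESeq2 gave 10971 of the 11549 genes no adjusted p. With sex as a block edgeR called 60, 40 and 14 genes, and without a filter on low counts 35, 35 and 46. The smallest p in cones belonged to Nmt1, an N-myristoyltransferase (−0.76 ± 0.11, edgeR adjusted p = 0.39), followed by Heg1 (0.65 ± 0.11), Krt18 (0.59 ± 0.11), Rd3l (−0.53 ± 0.11) and Plekhb1 (−0.43 ± 0.09). In rod bipolar cells the metallothioneins Mt2 (0.53 ± 0.09) and Mt1 (0.43 ± 0.09) and the actins Actb (−0.40 ± 0.08) and Actg1 (−0.34 ± 0.07) did not pass, with edgeR adjusted p from 0.137 to 0.207. In cone bipolar cells Dstn, an actin-depolymerising protein, had −0.39 ± 0.06 (edgeR adjusted p = 0.0654), with Sema3d at 1.44 ± 0.29, Kcnip4 at 0.36 ± 0.07, Snx32 at −0.55 ± 0.10 and Ntm at −0.37 ± 0.07. Without the WT female, WT male, NLGF female or NLGF male in turn, edgeR called 40, 21, 16 and 91 genes in cones, 17, 35, 19 and 35 in rod bipolar and 22, 37, 23 and 46 in cone bipolar cells.

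Glycolysis had medians of −0.16 in rod bipolar (camera adjusted p = 0.011), −0.21 in cone bipolar (0.00284) and −0.12 in amacrine cells (0.0281). With an estimated correlation none of the list calls in these classes was kept: the adjusted p was 0.873 for each rod bipolar list, 0.918 for the cone bipolar list, 0.906 for each amacrine list and 0.986 for the endothelial list. Adjusted over the list alone, 0, 9 and 1 of its genes fell there. In rod bipolar cells the ER chaperone list had a median of −0.11 (0.0289), with Calr at −0.28 ± 0.07 and 2 genes fallen when adjusted over the list alone. The respiratory chain had −0.05 there and ribosomal proteins 0.07 (0.048 each), with 1 gene fallen and 4 risen when adjusted over the list alone. Rod phototransduction transcripts, which mark rod RNA in other cells, had medians of 0.19 in rod bipolar (0.00368), −0.37 in amacrine (7.85e-08) and 0.62 in endothelial cells (4.43e-06). Adjusted over the list alone, 2 rose, 2 fell and 1 rose. The endothelial median was 1.28 between the females and 0.20 between the males, and the amacrine one −0.11 and −0.60. In endothelial cells these transcripts made up 0.713% of UMIs in the NLGF female, against 0.269%, 0.196% and 0.229% in the WT female, WT male and NLGF male. The mitochondrially encoded genes had −0.19 in amacrine cells (0.0255), with 2 fallen when adjusted over the list alone. The PERK/ATF4 list medians were −0.004 in cones, 0.06 in rod bipolar, −0.01 in cone bipolar, 0.05 in amacrine and 0.14 in endothelial cells, with 0 changed genes by edgeR in each and camera adjusted p from 0.533 to 0.99. Median and mean differed in sign in cone bipolar (mean 0.10, camera up) and endothelial cells (mean −0.006, camera down).

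**Figure D3:**
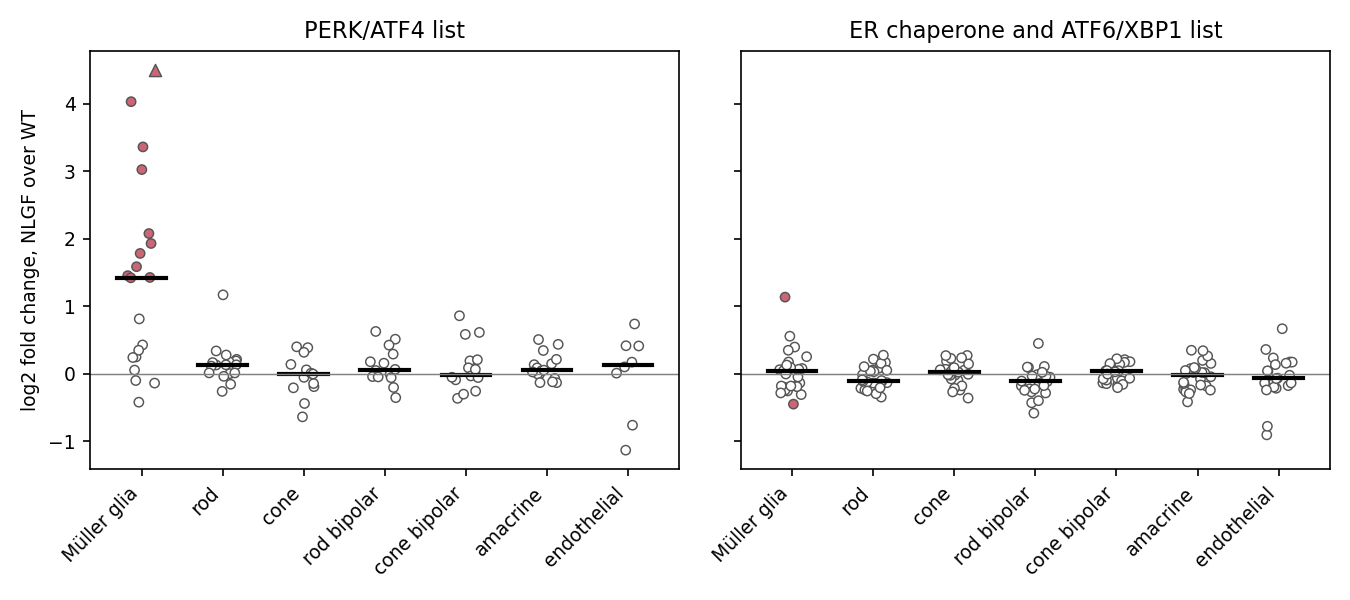
Log2 fold change of NLGF over WT for each measured gene of the PERK/ATF4 list (left) and the ER chaperone list (right) in 7 cell classes, with a bar at the median, filled points for genes past the adjusted p threshold of 0.05 and a triangle for Chac1, drawn at the upper limit. The PERK/ATF4 median is 1.42 in Müller glia and 0.13 in rods.

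In amacrine cells 1 of 11277 genes differed, with 494 at an unadjusted p under 0.05 and 3 by DESeq2. It was Vip, the vasoactive intestinal peptide of an amacrine subtype, with 0.241 ± 0.341 CPM in WT and 266 ± 255 in NLGF (edgeR adjusted p = 0.022). The NLGF female had 725 Vip UMIs in 5 of 140 cells and the NLGF male 190 in 4 of 198, against 1 UMI in the WT libraries. This call was lost with doublets kept, with the stricter cell filter, at the finer clustering and with centred components. Glra1, a glycine receptor subunit, had −1.82 ± 0.31 and Bhlhe22, an amacrine transcription factor, 0.49 ± 0.09, without passing (edgeR adjusted p = 0.114 and 0.16). Cntnap5a had −0.84 ± 0.17. Without the WT female, WT male, NLGF female or NLGF male in turn, edgeR called 55, 92, 39 and 46 genes, Vip among them each time. It called 13 with sex as a block and 64 without a filter on low counts.

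In endothelial cells 5 of 5189 genes differed (1 higher, 4 lower, edgeR), with 258 at an unadjusted p under 0.05 and 3 by DESeq2. The lower genes encode contractile proteins of smooth muscle: Acta2 (−6.87 ± 0.55), Tagln (−5.92 ± 0.70), Myh11 (−2.59 ± 0.32) and Tpm2 (−2.42 ± 0.38). Acta2 UMIs lay in 4 of 27, 2 of 20, 0 of 12 and 1 of 24 cells of the WT female, WT male, NLGF female and NLGF male. In the WT male 1 cell held 124 of 125 Acta2 UMIs and 1 cell 144 of 146 Tagln UMIs, and in the WT female 1 cell held 59 of 86 Acta2 UMIs, so the falls rest on a few cells. The higher gene, Gm42418, a transcript overlapping ribosomal RNA (0.52 ± 0.06), lay outside the naming rule and was named after its value was seen. Its call was lost without the WT female and, like that of Tpm2, with DESeq2. Hmgcs1, of cholesterol synthesis, had 1.31 ± 0.34 and Id1 0.71 ± 0.19, both with an edgeR adjusted p of 0.665. Without the WT female, WT male, NLGF female or NLGF male in turn, edgeR called 14, 22, 13 and 39 genes, 16 with sex as a block, 20 without a filter on low counts and 1 with counts thinned to the smallest library.

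The genotype effect was compared directly between Müller glia and rods. With edgeR it differed for 70 of 13615 genes, and 1162 had an unadjusted p under 0.05, with 45 differences higher in Müller glia and 25 lower. Among them were Trib3 (difference 3.87 ± 1.02 in log2), Mthfd2 (3.41 ± 0.41), Atf3 (3.06 ± 0.71), Slc7a1 (2.91 ± 0.54) and Tpbg, a Wnt-inhibitory glycoprotein (2.10 ± 0.56). Hba-a2 (−5.95 ± 1.24), Hbb-bs (−5.71 ± 0.59), Hbb-bt (−5.55 ± 1.07), Pdgfra (−4.48 ± 1.07) and Hba-a1 (−4.39 ± 1.09) had the lowest differences. The PERK/ATF4 list had a median difference of 0.89 over 22 genes, 18 of them above 0 and 8 of the 11 risen genes past the test (camera unadjusted p = 2.5e-12, and 0.035 with an estimated correlation). The count of 70 was 126 without the WT female, 49 without the WT male and 21 without either the NLGF female or the NLGF male. The Trib3, Atf3 and Tpbg differences did not pass without any 1 of the 4 libraries, and the Slc7a1 difference did not without the WT male or NLGF female. The Hba-a2, Hbb-bt, Pdgfra and Hba-a1 differences each failed without at least 1 library, the Hba-a2 one without the WT female. Without astrocyte-marker and haemoglobin-rich cells, a choice made after the data were seen, 95 genes differed, 84.2% of them higher in Müller glia, with 53 of the 70 shared. The 4 haemoglobin differences then ranged from −1.39 to 0.15 and did not pass.

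Cell class shares did not differ at the threshold. Müller glia made up 3.86% ± 1.16 of WT and 5.22% ± 0.665 of NLGF cells (SD, n = 2 each), a log2 ratio of 0.44 ± 0.27 (edgeR adjusted p = 0.386). The exact permutation test of 2 against 2 libraries cannot give a two-sided p below 0.333, and gave 0.333 for this share. Cone bipolar cells made up 4.53% ± 0.304 and 3.57% ± 0.313 (edgeR adjusted p = 0.323), and microglia 0.307% ± 0.0695 and 0.16% ± 0.0678 (edgeR adjusted p = 0.323). With 21, 29, 15 and 9 microglia the class was not tested for genes. Its Trem2, a lipid-sensing receptor of activated microglia, had 939.8, 1231, 1439.7 and 1675 CPM in the WT female, WT male, NLGF female and NLGF male. These values rest on 57, 98, 71 and 31 UMIs. The 95% counting intervals overlapped between the WT male (999 to 1500), NLGF female (1124 to 1816) and NLGF male (1138 to 2377). Tyrobp, also of the disease-associated microglia list, had 3050, 2713, 3630 and 2323 CPM in the same order, and Apoe was lower in both NLGF libraries. Ganglion cells (2, 5, 10 and 8) had the largest log2 ratio of shares, 1.43 ± 0.52 (edgeR adjusted p = 0.323), and horizontal cells (19, 11, 8 and 9) had −0.72 ± 0.39 (0.382). Both classes were too few for gene tests.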

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

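Results appear here because the genotype effect differed between Müller glia and rods by the interaction test. The tests on the comparison with rods, on the fallen genes and on haemoglobin were chosen after the result was seen.

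The effect differed for 70 genes. The log2 differences were 3.87 for Trib3, 3.41 for Mthfd2, 3.06 for Atf3, 2.91 for Slc7a1 and 2.10 for Tpbg, and −5.95 for Hba-a2, −5.71 for Hbb-bs, −5.55 for Hbb-bt, −4.48 for Pdgfra and −4.39 for Hba-a1. For Tpbg, both parts were below the threshold alone, with 0.55 ± 0.24 in Müller glia and −1.51 ± 0.53 in rods.

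Of 20 measured PERK/ATF4 genes 11 rose in NLGF Müller glia, and the list passed camera at the preset correlation and not with an estimated one (adjusted p = 0.258, unadjusted p = 0.0117). A change shared by all cell classes is argued against by the list's median difference of 0.89 between Müller glia and rods (camera unadjusted p = 0.035 with an estimated correlation). That p is for 1 list and compares with the unadjusted 0.0117, not with 0.258, and the rule that used it was written after the values were seen. Another mix of shallow and deep cells is argued against by the median of 1.43 in the deepest Müller cluster alone, beside 0.67 over 9 genes with 0 risen by edgeR in the shallowest, and astrocyte-marker cells by the median of 1.44 without them. An effect of the App genotype stays open as a hypothesis, beside differences between litters or preparations, which the labels do not give and 2 libraries per genotype do not separate. Of the 3 splits of the 4 libraries into pairs, 1, the real one, gave 119 genes and the highest other gave 7, and 3 splits are too few for a share under 0.05.

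Of the genes that fell in NLGF Müller glia, 12 had over 50% of their WT UMIs in the 9 and 8 astrocyte-marker cells of the WT female and WT male, and 42 did not. For the 8 genes chosen by their share in the WT female and not used to pick the cells, the median share in the marker cells of the WT male was 64.2%, against 3.73% of all Müller-class UMIs there. A few astrocytes counted with WT Müller glia are therefore a candidate source for these falls, and fewer sampled astrocytes or lower expression in NLGF astrocytes both stay open. For the other 42 genes the median log2 fold change was −0.72 with all cells and −0.60 without the marker cells, and 37 still passed. These genes were set apart by their low share, with a median of 7.25% of their WT UMIs in the marker cells. Leaving out these cells could therefore hardly move most of them and is no separate test. What the shares show is that most of their WT UMIs lay in other Müller-class cells. Genotype stays open for those 42.

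The haemoglobin genes were higher in NLGF rods. Without cells of at least 10 haemoglobin UMIs, 0 of the 4 genes was higher past the edgeR threshold, and their log2 fold changes ranged from −0.68 to −0.19, in line with single red blood cells counted among the rods. In the WT libraries the cells richest in haemoglobin, with 11776 and 8503 UMIs, lay in the unnamed clusters. More haemoglobin RNA spread over the NLGF rods as the source is argued against by the same values, the highest being −0.19 ± 0.40 for Hbb-bs, against 3.93 or more with all cells.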

How the results depend on the processing

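Subsets of Müller glia and of rods were chosen after the data were seen, and the other alternatives before. Of the named values that passed, these changed sign without passing then. Igfbp5 in Müller glia turned to 0.0673 with the strict filter and 0.18 without astrocyte-marker cells. Without haemoglobin-rich cells, Hbb-bt in rods turned to −0.31, Hbb-bs to −0.19, Hba-a2 to −0.54 and Hba-a1 to −0.68. The Hba-a1 difference between Müller glia and rods turned to 0.15 without both kinds of cells. Of the 119 Müller genes 4 changed sign in the shallowest cluster. No class share crossed the threshold in any alternative run. The strict cell filter was not run for endothelial cells, because a library then had fewer than 10.

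Müller glia had 119 changed genes, against 26 with no filter on low counts, 76 with thinned counts, 200 with doublets kept and 45 with DESeq2. Of the 119, 26, 74, 107 and 42 were shared. The deepest cluster alone gave 216 and the shallowest 0 by edgeR, with 3764 genes tested and 172 at an unadjusted p under 0.05 there. Leaving out a library gave 70 to 260, where the lone library of a genotype is assumed to vary like the others. The PERK/ATF4 median ranged from 0.67 to 1.44 over the alternatives, and the list's adjusted p from 1.06e-15 to 0.258. Its call was lost with camera at an estimated correlation (median 1.42, adjusted p = 0.258, unadjusted p = 0.0117). The correlation estimated for the list was −0.04, below the preset 0.01, which argues against correlated genes as the reason for this loss. That estimate rests on 2 libraries per genotype. A simulated list of 20 genes raised 2-fold had an unadjusted camera p of 0.0135 with an estimated correlation, so that setting had little power. The ER chaperone median ranged from −0.18 to 0.07, never past the threshold.

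Without a filter on low counts, rods had 104 changed genes, cones 35, rod bipolar 35, cone bipolar 46, amacrine 64 and endothelial cells 20. With thinned counts, rod bipolar had 2, cone bipolar 3, amacrine 2 and endothelial cells 1. With doublets kept, rods had 1, cones 3, rod bipolar 2, cone bipolar 4 and amacrine cells 0, and the difference between Müller glia and rods 109. With the strict filter, rods had 254, rod bipolar 3 and amacrine cells 0. At resolution 2, rod bipolar had 1 and amacrine cells 4. With centred components, rods had 1 (0 higher, 1 lower) and amacrine cells 0. Where amacrine cells had 0 with edgeR, 445 (doublets kept), 460 (strict filter) and 491 (centred) genes had an unadjusted p under 0.05, and DESeq2 was not run. DESeq2 called 3 in rods, 12 in cone bipolar (10971 genes got no adjusted p), 3 in amacrine and 3 in endothelial cells. Without haemoglobin-rich cells rods had 1. Leaving out a library gave 20 to 1069 in rods, 16 to 91 in cones, 17 to 35 in rod bipolar, 22 to 46 in cone bipolar, 39 to 92 in amacrine, 13 to 39 in endothelial cells and 21 to 126 for the difference. The cause was not tested for these shifts, except for the haemoglobin-rich cells, which the alternative removes.

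Sex as a replicate block gave 217 genes in Müller glia, 133 in rods, 60 in cones, 40 in rod bipolar, 14 in cone bipolar, 13 in amacrine and 16 in endothelial cells. The block leaves fewer degrees of freedom for the spread between libraries. Across the genotypes the labels pair libraries by sex alone, and do not give litters or batches. The female minus male differences of both genotypes correlated across genes between −0.07 and 0.20. Of 46 named values past the threshold, 27 still passed with DESeq2 and 46 with the block. With the differences between Müller glia and rods included, 43 of 56 passed with doublets kept and 55 with RLE factors.

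At the depth of these libraries 21.2% of 1.5-fold changes were recovered in simulated Müller counts, and depth itself was not varied there.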

Other observations

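The test of the tRNA synthetases was chosen after the result was seen. Several aminoacyl-tRNA synthetases stood among the risen Müller genes, so the whole family was compared. Of 20 measured cytosolic synthetase genes 7 rose with edgeR (Yars, Cars, Aars, Iars, Tars, Lars and Nars) and 0 fell, and of 15 mitochondrial ones 0 rose. Of the 7, Yars, Tars, Lars and Nars did not pass without the NLGF female, Tars and Nars did not without the NLGF male, and with DESeq2 Cars and Iars alone passed. The median log2 fold change was 0.25 over the 20 genes, which include those that prompted the comparison, and 0.12 over the mitochondrial ones. The 13 cytosolic genes that did not pass alone had a median of 0.0274 (camera adjusted p = 0.956), which leaves open whether the cytosolic genes rise as a group.

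In the untested microglia, Apoe, a lipid carrier, had 9629 CPM in the WT female and 3128 in the WT male, and 1784 and 1891 in the NLGF female and male. The complement gene C1qa had 5507, 5276, 5049 and 3403, and the homeostatic receptor P2ry12 841, 1294, 892 and 648.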
